A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

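The series holds 10 Structure-seq samples of the budding yeast Saccharomyces cerevisiae. Structure-seq reads RNA structure in living cells: dimethyl sulfate (DMS) methylates unpaired adenines and cytosines, reverse transcription stops at the modified bases, and the stops are mapped by sequencing. The wild type (WT) was the laboratory strain BY4741, and in the second strain, dbp2Δ, the gene of the DEAD-box RNA helicase Dbp2 was replaced with a kanamycin-resistance cassette. Per the labels' protocols, mid-log cultures in rich medium with 2% glucose at 30 °C received 10 mM DMS for 10 min or no DMS, and polyadenylated RNA was purified before library construction. Each of the 2 treatments has 3 WT and 2 dbp2Δ samples, described in the labels as biological replicates; the dbp2Δ samples carry the numbers 1 and 3. Groups, replicate numbers and sequencing lanes were taken from the labels.

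The deposited count matrix holds raw read counts of the 5 untreated samples over 7706 features, an ORF row and an ext row for each of 3853 genes. Its columns were matched to samples through the column names given in the labels. The deposited per-nucleotide DMS reactivities, 1 list for each of the 5 DMS-treated samples, are scores of the authors' own scale and were never negative. A value was given at 60.1%, 69.8% and 60.1% of positions in WT samples 1, 2 and 3 and at 75.2% and 72.2% in dbp2Δ samples 1 and 3. Of the positions with a value, 75.5%, 76.9% and 74.4% were at 0 in WT and 79.1% and 81.5% in dbp2Δ. Both shares were thus higher in each dbp2Δ library than in any WT library. Per the submitters' processing notes, Trimmomatic 0.36, cutadapt 1.9.1, STAR 2.5.2b, edgeR 3.14.0 and genome build R64 were used, with no role or order given. How reads were assigned to ORF and ext rows, where an ext region begins and ends, whether strand was used, how shared reads of near-identical genes were treated, and how treated and untreated reads were turned into a reactivity are not given in the sources used here. The ext rows were taken as the region beyond the gene's reading frame. In the reactivity files, 829 transcripts had no ext annotation. Among transcripts matched to RefSeq, those of genes with an ext annotation exceeded the RefSeq span of the gene by a median of 1213 nt, against 350.5 nt in those without. Gene symbols and positions came from the RefSeq table of assembly R64, which matched 4258 of the 4682 identifiers; positions are those of the R64 build. Of the 3477 genes with an ext annotation, a RefSeq match and a known strand, 67.2% had a gene on the opposite strand within 1000 nt of their end and 23.1% had one on the same strand.

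Untreated counts were tested with edgeR 4.0.16 in R 4.3.3: rows were filtered with filterByExpr by genotype, scaled with TMM and fitted with the quasi-likelihood model with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. ORF and ext rows entered the same fit. Because the ext rows rose as a class, the median ORF row lay at -0.29 on the log2 scale in this fit, and ORF and ext changes are therefore given relative to the median ORF row, while the adjusted p-values are those of the fit. CPM values use the plain column totals. The ext to ORF ratio of a gene was tested in a model over both regions with a genotype-by-region interaction and a term for each sample. The sample term absorbs any scaling of a whole library, so TMM, RLE and raw totals hardly move this test (1187, 1188 and 1189 calls). The share of ext counts and the mean reactivities were compared between 3 and 2 samples with two-sided exact permutation tests over the 10 splits, whose smallest possible p is 0.1. PCR copies cannot be told from separate molecules here, so counting intervals cover counting error only.

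Bases are not marked in the reactivity lists and no genome sequence was used, so all positions with a value in all 5 libraries were taken, not adenines and cytosines alone, and untranslated regions were not placed. Infinite values, 1372 to 1582 per library, were treated as missing. The first line of each transcript carries a number of unknown meaning, the same in all 5 files, which was not used. Of 4681 transcripts, 4169 had at least 50 positions with a value in all libraries, and 1427 of these had on average at least 30% of positions above 0 and were tested. Mean reactivity per transcript and in 50 nt windows (at least 10 positions) was tested as log2(value + 0.01) with limma 3.58.1 (lmFit, and eBayes with a trend), so fold changes are on the log2(value + 0.01) scale. The Gini index of the reactivities, which is 0 for an even profile and rises towards 1 as the signal concentrates in few positions, was tested the same way without a log. Depth behind the reactivities is unknown.

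Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The lists fixed before the data were examined were DEAD-box helicases, glycolysis and fermentation, gluconeogenesis and glyoxylate cycle, hexose transporters, GAL genes, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, snoRNA genes, mRNAs attenuated by Nrd1-Nab3-Sen1, heat shock proteins, the PHO regulon, cleavage, polyadenylation and termination factors, mRNA export, auxotrophic markers, a-specific and alpha-specific genes, mitochondrially encoded genes and intron-containing genes. No snoRNA passed the count filter, the list of intron-containing genes could not be filled from the tables used, and lists with fewer than 3 tested members were not tested as sets. The same lists were tested on the ext to ORF ratio and on the Gini index, which was decided after the data were seen. Correlations across genes used 100000 permutations.

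Named genes follow a rule fixed before the data were examined. DBP2, the 2 annotated genes on either side of it and the markers HIS3, LEU2, MET17 and URA3 are given first. Then, for counts, ratios, transcripts and windows, come the 10 increases and 10 decreases of largest fold among calls whose genotypes do not overlap, or the 5 smallest p of each direction where fewer than 5 pass, and up to 4 members of smallest p from each list. The Gini calls and the ribosomal protein windows named below were chosen after their values were seen.

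Each fitting step was tested on simulated data with known changes. For counts (5637 simulated rows), 41.8% of rows changed by 1 log2 unit and 79.6% of rows changed by 2 were recovered, with 2.54% false calls. For the ratio (2220 genes), 13% and 66% were recovered and 10.2% of the calls were false, above the nominal rate. For mean reactivity (1427 transcripts), 100% were recovered at both sizes. For the Gini index (1427 transcripts), 67% of changes of 0.05 and 100% of changes of 0.1 were recovered, with 3.47% false calls. For windows (41536), 2% and 4% were recovered and 14.3% of the calls were false. Window calls and absent window calls are therefore both weak evidence. In all simulations a small part of the features changed, with as many rises as falls, and no class of rows shifted together. The rates need not hold for the real count and ratio fits, where ext rows rose as a class.

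Alternatives covered DESeq2 1.42.0, RLE factors, raw totals, other count filters, the replicate number and the lane as blocks, separate fits of ORF and ext rows, other pseudocounts, filters, scalings, window sizes and ends, and each library left out in turn. The fits of ORF and ext rows apart, the separate scaling of ext and ORF columns, the 20% filter, positions with a value in each library by itself, windows without a 0 or with at least 40 valued positions, the last 100 valued positions, the ratio in the relation of structure and counts, the lane values of the ext share and the additional gene lists were chosen after the data were seen. Per-library values and permutation tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots were drawn with matplotlib 3.10.9.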

Results

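Dbp2 is an RNA helicase that acts on RNA as it is made, and the study asked how its loss changes RNA structure and the processing of mRNAs. The data comprised read counts over the ORF and ext regions of 3853 genes in untreated cells, 3 WT and 2 dbp2Δ samples, and DMS reactivities along 4681 transcripts in 3 WT and 2 dbp2Δ treated samples. The untreated libraries held 6881446, 16885737 and 5132445 counts in WT samples 1, 2 and 3 and 11599867 and 8524861 counts in dbp2Δ samples 1 and 3. A count of 0 in these libraries allows a level of up to 0.178 CPM in the deepest and 0.585 CPM in the shallowest. The 10 most abundant rows took 14.2% to 23.9% of the counts in WT and 9.93% to 12.4% in dbp2Δ. All pairs of replicates differed by more than sampling noise, with chi-square values of 10.7 to 225 per degree of freedom, and each library was kept as its own replicate.

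DBP2 itself (YNL112W, chromosome XIV, 413639 to 416281) was read first as a check of the labels. Its ORF stood at 859, 1026 and 904 CPM in WT and at 51.0 and 13.5 CPM in dbp2Δ, a log2 change of -5.39 ± 0.52 (SE) relative to the median ORF (adjusted p = 0.000827, edgeR quasi-likelihood test). The dbp2Δ libraries thus held 592 and 115 DBP2 ORF counts, 5.49% and 1.45% of the WT mean CPM. The ext region of DBP2 fell far less, by a log2 change of -0.73 ± 0.27 (adjusted p = 0.0225, edgeR), and kept 84.5% and 87.2% of its WT CPM. Among the neighbouring genes, CYB5, which encodes cytochrome b5, changed by -0.63 ± 0.16 and NOP15, a ribosome biogenesis factor, by -0.28 ± 0.16 (adjusted p = 0.00546 and 0.0285, edgeR), both relative to the median ORF. In plain CPM NOP15 was at 706, 960 and 646 in WT and at 937 and 855 in dbp2Δ, so its direction depends on the scaling. YNL115C stood at 0.25 ± 0.19 (adjusted p = 0.901, edgeR). RPC19, between DBP2 and YNL115C, was not analysed here.

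Markers of the strain background separated the genotypes as well. LYS2 (YBR115C, chromosome II, 469748 to 473926), which encodes the aminoadipate reductase of lysine synthesis, fell from 177, 179 and 159 CPM in WT to 7.93 and 3.05 CPM in dbp2Δ, a log2 change of -5.48 ± 0.36 (adjusted p = 0.000282, edgeR). MET17 (YLR303W, also called MET15, chromosome XII, 732542 to 733876), the O-acetylhomoserine sulfhydrylase of methionine synthesis, rose from 5.52, 2.78 and 2.14 CPM to 94.6 and 91.5 CPM, a log2 change of 4.22 ± 0.40 (adjusted p = 0.00107, edgeR). The labels give both strains a deletion of this gene and mention no lysine marker. Other differences between the strains can therefore not be separated from the loss of Dbp2 in the comparisons below. LEU2, deleted in both strains, had 1 to 5 ORF counts per library and was not tested, and HIS3 and URA3 were not analysed here.

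**Figure D1:**
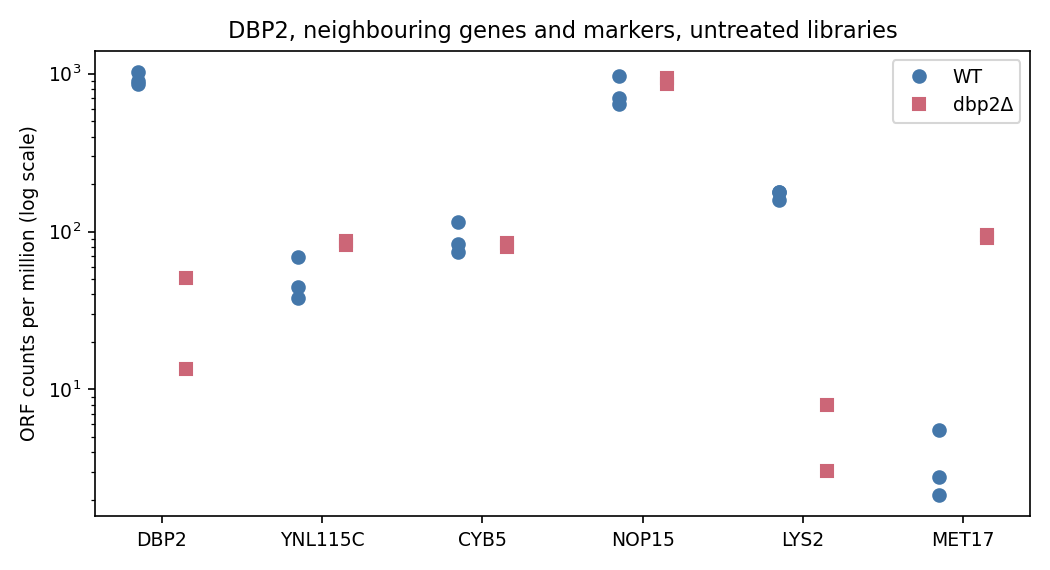
ORF CPM on a log axis for DBP2, the neighbouring genes and the markers LYS2 and MET17, with 1 point per untreated library (circles WT, n = 3; squares dbp2Δ, n = 2). DBP2 and LYS2 lie at 51.0 CPM or less in dbp2Δ, and MET17 rises to 91.5 and 94.6 CPM.

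The ext regions took a larger part of the counts in dbp2Δ. They held 3.94%, 2.52% and 4.24% of all counts in WT and 6.84% and 6.34% in dbp2Δ, means of 3.57% ± 0.920 (SD, n = 3) and 6.59% ± 0.349 (SD, n = 2). The share was 1.85 times as large in dbp2Δ, and every dbp2Δ library lay above every WT library (exact permutation test, two-sided, p = 0.1, the smallest this design allows). In the median gene, ext counts per 100 ORF counts were 2.59 ± 0.263 in WT and 6.01 ± 0.302 in dbp2Δ (exact permutation p = 0.1). Within lane 2 the share was 2.90 percentage points higher in dbp2Δ, and within lane 4 it was 3.82 points higher, with 1 library of each genotype per lane. Lane 3 held a WT library only.

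**Figure D2:**
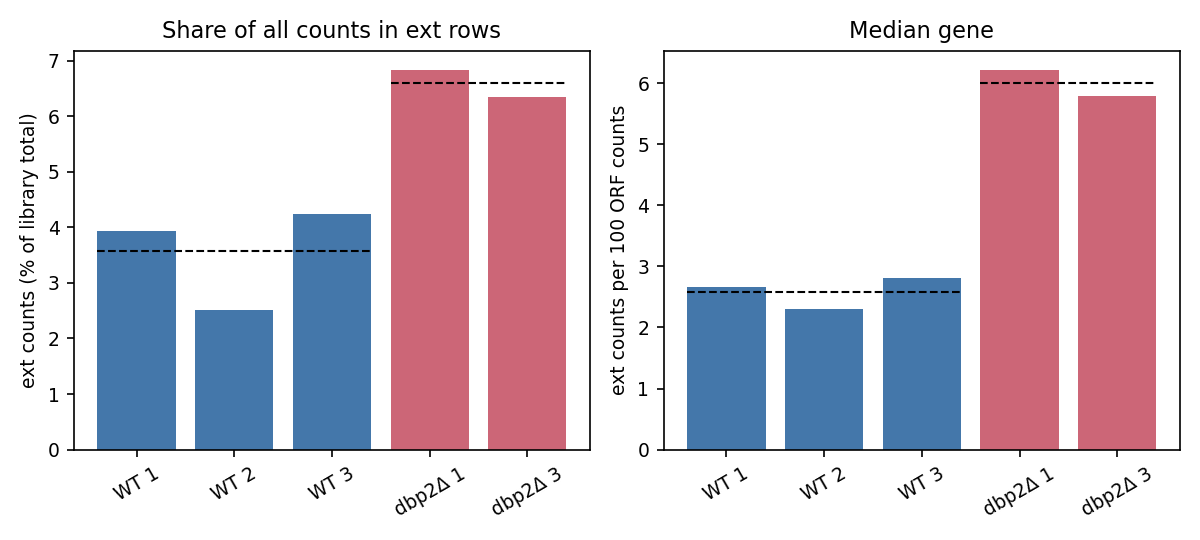
Share of counts in ext regions in percent of the library total (left) and ext counts per 100 ORF counts in the median gene (right), with 1 bar per untreated library and dashed lines at the genotype means. The dbp2Δ bars stand at 6.84% and 6.34%, above all WT bars.

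Gene by gene, the ext to ORF ratio rose in 1130 of the 2220 genes tested and fell in 57, and 88.8% of the genes had a positive change, with a median of 2.47-fold (log2 1.31). Of the genes with a higher ratio, 316 had an ORF that was called lower when ORF rows were fitted alone, 88 had one called higher and 726 had one not called. Ribosomal protein genes led the list: RPL41A went from 0.00317 ± 0.00368 to 0.161 ± 0.0707 ext counts per 100 ORF counts, RPS9A from 0.0172 ± 0.00971 to 0.567 ± 0.283 and RPS15 from 0.0213 ± 0.0140 to 0.334 ± 0.0177 (means ± SD, n = 3 and 2). RPL8A reached 138 ± 28.6 ext counts per 100 ORF counts in dbp2Δ against 7.31 ± 0.709 in WT, from 3005 to 5127 ext counts per dbp2Δ library, a log2 change of 4.22 ± 0.35 (adjusted p = 0.000253, edgeR). RPS24A rose from 0.149 ± 0.0317 to 2.87 ± 1.32, and ADH2, the alcohol dehydrogenase used in growth on ethanol, by 4.27 ± 0.54 on the log2 scale (adjusted p = 0.000885, edgeR). DBP2, LSC2, the beta subunit of succinyl-CoA ligase, YER188C-A and THI2, a regulator of thiamine synthesis, completed the 10 largest increases. Their adjusted p lay between 0.000551 and 0.0121 (edgeR). The rise of DBP2 follows the loss of its ORF, since its ext region did not rise and kept 84.5% and 87.2% of its WT CPM. The ADH2 ORF had a log2 change of -3.32 relative to the median ORF, which raises its ratio too. ADH2 had 9, 5 and 10 ext counts in WT and 40 and 19 in dbp2Δ. LSC2, YER188C-A and THI2 had no more than 1 WT ext count each. As a list, ribosomal proteins had a higher ratio in 76 of 85 tested genes and in 78 when p was adjusted over the list alone. Their median rise was 4.53-fold (camera on ranked statistics, adjusted p = 8.2e-09, preset correlation). This form of the test takes no estimated correlation, so that check was not made. The median log2 ratio change was 2.18 in the list against 1.31 over all genes, and its ORFs had a median log2 change of -0.89 relative to the median ORF. A lower ORF raises the ratio, so the list's excess over other genes cannot be told from its ORF fall. Most ribosomal protein genes have a near-identical copy and their counts are uncertain, but all 12 tested genes with a single symbol had a higher ratio as well, with a median of 6.87-fold. This split by copy was chosen after the data were seen.

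The ratio fell most in YML122C, an uncharacterised gene whose ext region had 159 ± 5.97 CPM in WT and 3.85 ± 1.14 CPM in dbp2Δ. In WT it had 35066.7, 19357.1 and 10562.5 ext counts per 100 ORF counts, and a gene on the same strand lies 238 nt from its end. The ext reads therefore need not come from YML122C, and whether they belong to that neighbour was not tested. COX26, a small subunit of cytochrome c oxidase, fell from 71.5 ± 100 to 1.41 ± 0.341 ext counts per 100 ORF counts, with WT sample 3 at 187.5 and the other WT libraries at 11.4 and 15.6. The ext counts of COX26 were 8, 7 and 15 in WT and 28 and 21 in dbp2Δ, so they did not fall with its ratio. HSP26, a small heat shock chaperone, fell from 30.0 ± 14.3 to 1.63 ± 0.671. Its ORF rose by 3.00 on the log2 scale relative to the median ORF, which lowers its ratio. PDR12, a transporter of weak acids, had a log2 change of -2.44 ± 0.49 (adjusted p = 0.00378, edgeR). REA1, RSF2, LAM1, YOL160W, YER076C and FMP33 completed the decreases, with log2 changes between -3.50 and -2.61 and adjusted p between 0.00143 and 0.0304 (edgeR). No other list than ribosomal proteins differed from the remaining genes in this ratio. The smallest other adjusted p was 0.253, for heat shock proteins, of which 3 of 8 had a higher and 2 a lower ratio, 4 and 2 when adjusted over the list alone (camera on ranked statistics). DEAD-box helicases had a higher ratio in 8 of 11 genes (9 when adjusted over the list alone), the deleted DBP2 among them. Cleavage, polyadenylation and termination factors had one in 8 of 10 (8) and mRNA export factors in 6 of 9 (6). The count of genes rests on both dbp2Δ libraries: without dbp2Δ sample 1, 7 genes passed, and without dbp2Δ sample 3, 167, while the median log2 change stayed at 1.23 and 1.36. When ext and ORF columns were scaled apart, which removes the shift common to all genes, 70 genes had a higher and 125 a lower ratio. A fit with only rows of a mean count of at least 50 called 711 higher and 40 lower among 987 genes.

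Across all rows, 2370 of 5754 passed the test: 343 ORFs were higher and 1159 lower in dbp2Δ among 3486 tested, and 766 ext rows were higher and 102 lower among 2268. The split depends on scaling. Raw column totals gave 1316 higher and 151 lower ORFs with 1567 higher and 32 lower ext rows. A fit of ORF rows alone gave 627 higher and 600 lower, and a fit of ext rows alone 108 higher and 205 lower. All 343 higher ORFs and 600 of the lower ones were shared with the fit of ORF rows alone. With the lane as a block, 797 rows passed (111 higher and 350 lower ORFs among them), and without dbp2Δ sample 1 or 3, 1100 and 1187. The median ext row lay at 0.91 and the median ORF at -0.29 on the log2 scale of the joint fit, and at 1.70 and 0.51 with raw totals.

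Of the 10 largest rises, those of YFR057W and DPA10 were in ORFs and the others in ext regions. The ext region of TPO2, a polyamine exporter of the plasma membrane, went from 4.27 ± 3.36 to 231 ± 106 CPM, that of YRO2, a membrane protein of the Hsp30 family, from 5.82 ± 2.78 to 284 ± 82.3 CPM, and that of YGP1, a secreted glycoprotein, from 2.64 ± 2.06 to 105 ± 13.0 CPM. Their log2 changes relative to the median ORF were 5.31 ± 0.64, 5.12 ± 0.43 and 4.81 ± 0.52 (adjusted p = 0.00184, 0.000827 and 0.0014, edgeR). The ORF of YFR057W, an uncharacterised gene, had 0 counts in all WT libraries and 32 in dbp2Δ, at least 15.3-fold higher against a floor of 3 counts over the pooled WT libraries. The ext regions of DDR2, SOL4, MET17 and YER188C-A had 1 pooled WT count each against 55 to 62 in dbp2Δ, that of NCA3 had 2 against 103, and the ORF of DPA10 had 6 against 169. A higher ext row need not mean a higher ext to ORF ratio. The MET17 ORF rose as well, by 4.22 ± 0.40 on the log2 scale, and its ratio was not called (log2 1.30). Among the ext regions named here, only that of YER188C-A belongs to a gene with one of the 10 largest ratio rises. The calls of YFR057W, DDR2, SOL4 and YER188C-A were lost without dbp2Δ sample 3 (adjusted p = 0.0664, 0.0515, 0.0633 and 0.0732, edgeR).

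The largest falls after YML122C were in ORFs. DAN1, a cell wall mannoprotein made without oxygen, fell from 66.3 ± 59.6 to 1.81 ± 0.241 CPM, PHM6, a gene of the phosphate response, from 142 ± 40.3 to 4.44 ± 0.306 CPM, and FIT3, a cell wall protein that helps to retain siderophore iron, from 1148 ± 1070 to 77.7 ± 17.2 CPM. LSO1, which is induced by iron shortage, fell from 146 ± 146 to 5.44 ± 1.60 CPM. The spread between WT libraries of DAN1, FIT3 and LSO1 was wide because WT sample 2 stood at 131, 2358 and 313 CPM. Log2 changes relative to the median ORF were -5.60 ± 0.91 for DAN1, -5.49 ± 0.25 for PHM6, -4.30 ± 0.74 for FIT3 and -5.16 ± 0.84 for LSO1 (adjusted p = 0.00325, 6.44e-05, 0.00376 and 0.00331, edgeR). PAU9, a seripauperin of a family of near-identical genes, and YHL012W, with 42 WT counts and 1 in dbp2Δ, also passed but lost their calls without either dbp2Δ library. The ext region of LYS2 had 59 WT counts and 2 in dbp2Δ.

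Ribosomal protein ORFs were lower in dbp2Δ. Of 96 tested, 83 fell, 88 when adjusted over the list alone, and none rose, with a median 1.85-fold below the median ORF (camera, adjusted p = 1.19e-14 at the preset correlation; adjusted p = 0.541 with an estimated correlation). RPS9A fell from 3456 ± 215 to 596 ± 30.1 CPM, RPL8A from 1123 ± 69.7 to 290 ± 14.3 CPM, RPS21A from 1570 ± 275 to 866 ± 55.6 CPM and RPS14B from 450 ± 84.3 to 263 ± 17.9 CPM. All 12 with a single symbol fell, with a median of 2.03-fold, as did 71 of 84 with a paired symbol. The number of calls was not stable: 42 were lower when ORF rows were fitted alone, 25 lower and 1 higher with raw totals, 8 lower with the lane as a block and 23 lower without dbp2Δ sample 1. The list's median stayed below that of all ORFs in each of these settings, by 0.59 to 1.17 log2 units over all settings.

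The PHO regulon, the genes of phosphate uptake and storage, fell in all 6 tested members, by a median of 5.11-fold relative to the median ORF (camera, adjusted p = 4.78e-10; adjusted p = 0.358 with an estimated correlation). PHM6 is given above, PHO89, a phosphate transporter, fell from 129 ± 44.2 to 22.2 ± 8.69 CPM, VTC1, a subunit of the vacuolar polyphosphate polymerase complex, from 383 ± 94.5 to 173 ± 17.8 CPM, and PHO5, the secreted acid phosphatase, from 147 ± 48.1 to 79.6 ± 9.65 CPM. With raw totals 5 of the 6 passed.

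Calls among genes of glucose breakdown were lower and calls among genes of respiration were higher, in part of each list. Among 10 tested glycolysis and fermentation genes, 7 fell, 9 when adjusted over the list alone, and none rose, with a median of 2.27-fold (camera, adjusted p = 0.000146; adjusted p = 0.541 with an estimated correlation). HXK2, the main hexokinase in glucose, fell from 1105 ± 246 to 333 ± 41.6 CPM, TDH2, a glyceraldehyde-3-phosphate dehydrogenase with close paralogs, from 3518 ± 117 to 1107 ± 72.4 CPM, and PGK1, phosphoglycerate kinase, from 1508 ± 154 to 633 ± 160 CPM. Raw totals gave 5 lower and 1 higher, and 3 passed with the lane as a block. Among 17 tested oxidative phosphorylation genes, 8 rose, 9 when adjusted over the list alone, and none fell, with a median of 1.73-fold (camera, adjusted p = 0.00043; adjusted p = 0.541 with an estimated correlation). QCR2 and COR1, core subunits of the cytochrome bc1 complex, rose from 61.6 ± 7.13 to 184 ± 11.7 CPM and from 71.7 ± 10.5 to 189 ± 1.37 CPM, and SDH3, a subunit of succinate dehydrogenase, from 57.4 ± 5.55 to 150 ± 7.99 CPM. Raw totals gave 14 higher and ORF rows fitted alone 12. None passed with the lane as a block, and without dbp2Δ sample 3, 1 was higher and 2 were lower.

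Of the mRNAs attenuated by the Nrd1-Nab3-Sen1 termination complex, 4 of 5 tested fell, all 5 when adjusted over the list alone (camera, adjusted p = 0.0404; adjusted p = 0.541 with an estimated correlation), among them ADE12, the adenylosuccinate synthase, from 317 ± 44.0 to 159 ± 23.4 CPM. Their median lay 0.40 log2 units below that of all ORFs, with raw totals as well, where 1 of the 5 passed. When ORF rows were fitted alone 2 passed. ADE12, with a log2 change of -1.51 relative to the median ORF, also belongs to the purine synthesis list given below. URA8, HRP1, IMD3 and IMD2 stood between -0.58 and -0.20. With the replicate number as a block the list was not called (adjusted p = 0.0993, camera). The other lists were not called as sets at the preset correlation, and none of the lists fixed in advance was called with an estimated one. Among heat shock proteins HSP26 rose from 28.7 ± 3.59 to 325 ± 55.2 CPM while 5 of 11 fell, 6 when adjusted over the list alone, including HSP10 and HSP60, the mitochondrial chaperonins, from 334 ± 56.1 to 139 ± 1.62 and from 687 ± 84.1 to 336 ± 37.3 CPM (list adjusted p = 0.0874, camera). In the gluconeogenesis list ADH2 fell from 320 ± 99.2 to 47.2 ± 1.05 CPM and ICL1, isocitrate lyase, rose from 14.8 ± 3.07 to 53.6 ± 12.5 CPM, with 2 higher and 2 lower of 9, 3 and 3 when adjusted over the list alone (list adjusted p = 0.314). Of 17 DEAD-box helicases 7 fell, also 7 when adjusted over the list alone (list adjusted p = 0.111, camera), and these include the deleted DBP2 itself. DBP5 and SUB2, which act in mRNA export, fell from 626 ± 149 to 396 ± 1.64 and from 751 ± 87.1 to 558 ± 22.2 CPM. Lower calls numbered 15 of 30 in ribosome biogenesis with 1 higher, 7 of 11 in mRNA export, 6 of 18 among cleavage, polyadenylation and termination factors and 3 of 8 among hexose transporters (list adjusted p = 0.255, 0.111, 0.674 and 0.356, camera). Adjusted over each list alone, these were 15 lower with 2 higher, 8, 6 and 4. The direction of the calls in these lists hangs on the scaling. With raw totals, calls were 8 higher and 0 lower in ribosome biogenesis, 3 higher and 1 lower in mRNA export, 6 higher and 0 lower among cleavage, polyadenylation and termination factors, 7 higher and 2 lower among DEAD-box helicases and 6 higher and 1 lower in the gluconeogenesis list. With ORF rows fitted alone, the same lists had 2 higher and 5 lower, 0 and 3, 0 and 1, 1 and 5, and 3 and 1. Without dbp2Δ sample 3, lower calls were 3 in ribosome biogenesis, 3 in mRNA export, 1 among cleavage factors and 4 among DEAD-box helicases, and without dbp2Δ sample 1 they were 11, 2, 2 and 6. Raw totals gave 0 higher and 1 lower among hexose transporters, 2 and 5 among heat shock proteins, 2 and 0 among GAL genes, 3 and 0 among mitochondrially encoded genes and 2 and 1 among a-specific genes. None of 5 GAL genes passed (list adjusted p = 0.599). OLI1, a mitochondrially encoded subunit of the ATP synthase, rose from 20.8 ± 1.70 to 83.6 ± 31.2 CPM, the only call of 5 mitochondrially encoded genes (list adjusted p = 0.0874), and 2 of 5 a-specific genes fell, BAR1 and MFA1, 3 when adjusted over the list alone (list adjusted p = 0.355). The alpha-specific genes STE3 and MF(ALPHA)2 were not called (adjusted p = 0.22 and 0.49), and STE3 stood at 5.38 ± 1.63 CPM in WT and 5.46 ± 2.23 CPM in dbp2Δ.

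**Figure D3:**
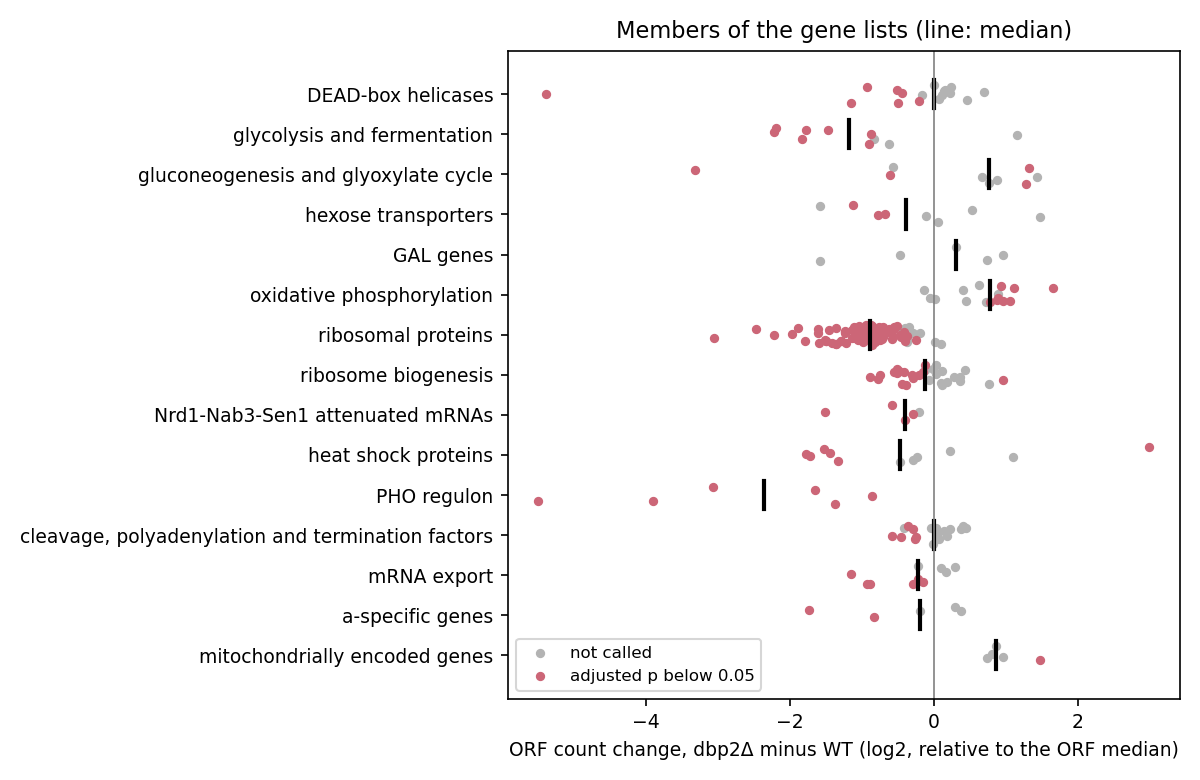
Log2 change of ORF counts, dbp2Δ minus WT and relative to the median ORF, for each tested member of the lists with at least 5 members, with the list median as a vertical line and calls in red. The PHO regulon median lies at -2.35 and the ribosomal protein median at -0.89, and that of oxidative phosphorylation at 0.79.

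DMS reactivity averaged over transcripts did not separate the genotypes. The mean over 1427 transcripts was 0.142 ± 0.0174 (SD, n = 3) in WT and 0.129 ± 0.00287 (SD, n = 2) in dbp2Δ (exact permutation p = 0.5). In the first 100 nt, WT and dbp2Δ means were 0.228 ± 0.0553 and 0.248 ± 0.00125 over 1244 transcripts (exact permutation p = 0.7), in the middle part 0.136 ± 0.0148 and 0.121 ± 0.00331 (exact permutation p = 0.3), and in the last 100 nt 0.0876 ± 0.0131 and 0.0699 ± 0.00261 over the 315 transcripts with values there (exact permutation p = 0.2). Over the last 100 positions with a value, which all 1427 transcripts have, reactivity was 0.115 ± 0.0134 in WT and 0.0947 ± 0.000190 in dbp2Δ, and both dbp2Δ libraries lay below all WT libraries (exact permutation p = 0.1). The share of positions above 0 was also lower in both dbp2Δ libraries, 33.7% ± 2.51 against 38.0% ± 0.834 (exact permutation p = 0.1). Lane 3 was the only lane with a treated library of each genotype, and there dbp2Δ sample 1 minus WT sample 3 was -0.0297 over whole transcripts and -0.0354 in the first 100 nt, where the genotype means differed in the other direction.

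**Figure D4:**
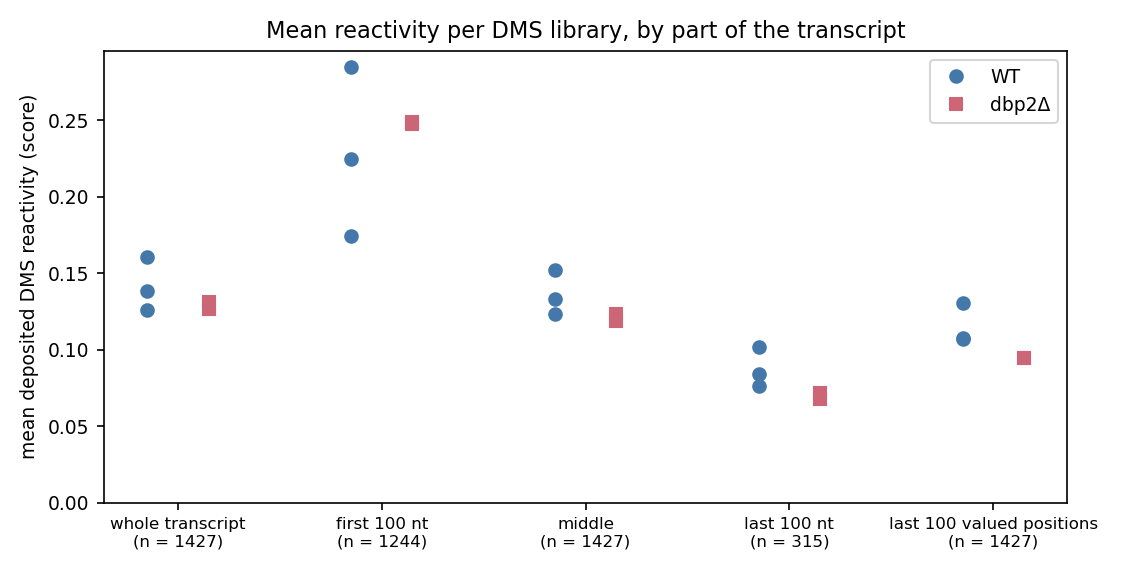
Mean deposited DMS reactivity (score) per treated library by part of the transcript, with the number of transcripts under each part (circles WT, n = 3; squares dbp2Δ, n = 2). Only over the last 100 valued positions and the last 100 nt do both dbp2Δ libraries lie below all WT libraries.

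Reactivity profiles of replicates resembled each other only moderately. Spearman's rho over 1977196 positions was 0.299 to 0.385 between WT libraries, 0.306 between the dbp2Δ libraries and 0.227 to 0.352 across genotypes. These values are across positions, which are not independent replicates.

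No single transcript passed the test of mean reactivity, although 86.3% had a lower value in dbp2Δ, with a median change of -0.13 on the log2 scale. The limma test called 0 of 1427, with 73 at an unadjusted p under 0.05 where 71.35 would be passed by chance. With each library centred on its median 153 had such a p, and with quantile normalization 141, again with 0 calls. Simulated changes of 1 log2 unit were recovered in full, but the changes named below were smaller. Neither smaller changes nor a shift of whole libraries was simulated. The smallest p of each direction belonged to RPL34A, 0.134 ± 0.0349 in WT and 0.0785 ± 0.0144 in dbp2Δ, SEM1, a proteasome subunit, 0.165 ± 0.0176 and 0.103 ± 0.00313 (adjusted p = 0.0585 for both, limma), and MFA1, the a-factor precursor, 0.124 ± 0.0125 and 0.188 ± 0.0274 (adjusted p = 0.15, limma). RPL39, CWP2 and NOP10 came next among lower values (adjusted p = 0.15, 0.233 and 0.233, limma) and DAD4, SPT4, ECM15 and RPL23B among higher ones (adjusted p between 0.7 and 0.818, limma). No gene list differed from the other transcripts in mean reactivity (smallest adjusted p = 0.803, camera). The count of calls stayed at 6 or fewer in all settings that kept every library, and it was 24 without WT sample 2 and 8 without WT sample 3.

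The Gini index rose in 84 transcripts and fell in 5, so the signal was concentrated in fewer positions in dbp2Δ for most of the calls. It rose in ADE17, an enzyme of purine synthesis, from 0.813 ± 0.0223 to 0.914 ± 0.0246, in VTC3 and VTC4 of the polyphosphate polymerase complex from 0.835 ± 0.0207 to 0.928 ± 0.0112 and from 0.819 ± 0.0176 to 0.901 ± 0.00278, and in COX17, a copper chaperone for cytochrome c oxidase, from 0.839 ± 0.0239 to 0.930 ± 0.0262. HXK2 went from 0.822 ± 0.0150 to 0.897 ± 0.00813. Their adjusted p ranged from 9.21e-09 to 0.00125 (limma). Of heat shock proteins 4 of 11 rose, 5 when adjusted over the list alone, among them HSP104, HSP82, HSP42 and SSA2. The falls were in RPL23A, RPS14A, RPL41A, RPS12 and SND3, the last a protein targeting factor, for example from 0.933 ± 0.00779 to 0.896 ± 0.0115 in RPS12 (adjusted p = 0.0022, limma). As a list, ribosomal proteins stood below the other transcripts, with a median change of 0.00237 against 0.0240 over all transcripts and 4 lower calls, also 4 when adjusted over the list alone (camera, adjusted p = 1.89e-21; adjusted p = 0.263 with an estimated correlation), and 2 of 3 PHO regulon transcripts rose, 3 when adjusted over the list alone (camera, adjusted p = 7.04e-06; adjusted p = 0.263 with an estimated correlation). The mean index of a library was 0.849 ± 0.0137 in WT and 0.872 ± 0.00843 in dbp2Δ (exact permutation p = 0.2). When each library was centred on its median, 28 of the 84 rises and all 5 falls were still called, with 28 rises and 35 falls in all. Quantile normalization gave 47 and 43. Some transcripts with a higher index had far lower ORF counts in untreated dbp2Δ cells. Relative to the median ORF, log2 count changes were -3.13 for ADE17, -2.22 for HXK2 and -1.72 for SSA2. HSP82, HSP104 and HSP42 stood at -0.47, 0.23 and 1.10 and were not called. All 6 tested PHO regulon ORFs were lower. Read depth as a source of the Gini rises is weighed below and stays open. Leaving out WT sample 1, dbp2Δ sample 1 or dbp2Δ sample 3 left 7, 7 and 5 calls, and leaving out WT sample 2 gave 450.

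In 50 nt windows, 123 of 41536 rose and 15 fell, in 106 transcripts. Ribosomal protein transcripts held 58 of these 138 windows, 56 of them higher in dbp2Δ, and 30 of 111 such transcripts had at least 1 called window (27.0%) against 5.78% of the others (Fisher's exact test, p = 2.46e-11). Of the 53 called windows without a library at 0, 48 were in ribosomal protein transcripts. In RPL19A the window from position 601 of the transcript rose from 0.00210 ± 0.000531 to 0.0246 ± 0.000710, and in RPS21A that from position 251 rose from 0.00126 ± 0.000296 to 0.0185 ± 0.00145, with RPS9B at position 351 going from 0.00291 ± 0.000341 to 0.0236 ± 0.000923 (adjusted p = 0.00756, 0.0068 and 0.0102, limma). GLC7, the catalytic subunit of protein phosphatase 1, rose from 0.00462 ± 0.00123 to 0.0460 ± 0.000784 at position 651, while RPL8A fell from 0.0721 ± 0.0128 to 0.000962 ± 0.00117 at position 901. The WT means of the named rises lay below the pseudocount of 0.01, where the log2 scale compresses both change and spread. With a pseudocount of 0.1, 58 windows passed in place of 138. Whether the enrichment follows the abundance of these transcripts was not tested. These examples and the enrichment were chosen after the values were seen.

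The windows of largest change by the fixed rule were all listed at 0 in at least 1 library of 1 genotype. NOP8, SKI6, MFA1, GIM5, TIM23, GLO3, RPS1B, RPL6A, WRS1 and RIX7 had a window at 0 in all 3 WT libraries and at a mean of 0.243 to 0.809 in dbp2Δ, from 11 to 20 positions with a value. MHF1, RVB2, TOM20, PHO86, ADE17, RRP45, RPS30B, EMC10 and FAR8 had a window at 0 in both dbp2Δ libraries and at 0.205 to 0.675 in WT, and CUB1 had one at 0 and 0.00559 in dbp2Δ and at 0.293 ± 0.111 in WT. Adjusted p-values of these windows ran from 0.0035 to 0.0471 (limma). Among all higher windows 68 had every WT library at 0, and among the lower ones 13 had both dbp2Δ libraries at 0. At least 1 library was at 0 in 85 of the 138 called windows, against 5.15% of all tested windows. Of all called windows, 41 were the last with values in their transcript. Windows were not placed relative to the reading frame. Transcripts of genes with an ext annotation exceeded the gene's span by a median of 1213 nt, so some windows may lie in ext regions. The median number of valued positions was 28 over all called windows and 50 over all tested windows. No window passed without WT sample 1 or WT sample 3, while 75 passed without WT sample 2 and 312 and 321 passed without dbp2Δ sample 1 and 3.

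Changes of reactivity near the end of the deposited transcripts were unrelated to changes of counts across genes. These ends need not be mRNA ends, because transcripts of genes with an ext annotation exceeded the gene's span by a median of 1213 nt. For the last 100 nt, Spearman's rho was 0.0272 and Pearson's r 0.00965 across 159 genes (permutation p = 0.732, adjusted p = 0.775 over 6 relations computed). For whole transcripts rho was -0.115 and r -0.150 across 1139 genes (permutation p = 0.00011, adjusted p = 0.00066), so transcripts whose reactivity was lower tended to have higher ORF counts. With the ext to ORF ratio in place of counts, rho was 0.0240 across 141 genes for the last 100 nt (permutation p = 0.775) and 0.0293 across 868 genes for whole transcripts (permutation p = 0.388). Genes are not independent replicates.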

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

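The comparison of the median gene in the background test and the test of a library-wide Gini shift were chosen only after the results were seen. The lysine and sulphur lists were written after the LYS2 and MET17 changes were seen, but before the values of their other genes were. The YML122C, PHM6 and LSO1 values beside the carry-over test were picked after they were seen. The other tests were set before the tested values were seen.

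MET17 drew attention in data outside the comparisons above: 88.2% of its transcript positions had a deposited reactivity in dbp2Δ (mean of 2 libraries) against 24.8% ± 3.96 (SD, n = 3) in WT. LYS2 went the other way, with 14.2% ± 7.27 in dbp2Δ and 72.6% ± 6.78 in WT, and DBP2 had 61.5% ± 19.1 in dbp2Δ (75.0% and 48.0%) against 83.7% ± 1.63 in WT, so its loss is only partly visible in the treated libraries. The treated libraries therefore show the MET17 and LYS2 differences too. Regulation of the pathway was tested as an explanation. The other 4 tested lysine genes had a median log2 change of 0.23 (range -0.36 to 0.77), which argues against a lower lysine pathway as the cause of the LYS2 fall, and the other 3 sulphur genes had a median of 0.40 with MET10 at 1.08. That spread is too wide for the test to exclude a part for regulation, but none of the 3 came near the 4.22 of MET17. The labels give MET17 as deleted in both strains, and its 1097 and 780 ORF counts in dbp2Δ samples 1 and 3 go against that label. A pair of strains that differ at LYS2 and MET17 may account for both, but no test here bears on the strains' origin. If the strains do differ beyond DBP2, every difference between WT and dbp2Δ in counts, lists, ext share and reactivity is also a difference between strain backgrounds.

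Carry-over of WT RNA or reads was tested as the source of the counts left over DBP2 and LYS2 in dbp2Δ: no other ORF of at least 50 CPM in WT, 0 of 2232, fell below 0.5 times the percent that LYS2 kept, and DBP2 kept 1.19 and 0.816 times the percent of LYS2 in samples 1 and 3. Against it, LSO1 kept 2.95% in sample 1, less than the 4.62% of LYS2 and the 5.49% of DBP2, but its WT libraries ranged from 43.9 to 313 CPM. The ext region of YML122C (4.66 CPM in sample 1 against 153, 160 and 165 in WT) and the ORF of PHM6 (4.66 against 129, 187 and 109) kept a smaller part than LYS2 there as well. Carry-over is neither shown nor excluded. Counts from transcribed remains of either locus were not tested.

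The higher ext share could come from background that adds evenly to all ext regions, such as DNA, although the labels name a DNase step. The mean rise in ext CPM was 201 times as large in the top 10% of genes by ORF level as in the bottom 10%, but the ratio had no usable lower bound because the rise in the bottom 10% was near 0. In the median gene of the bottom 10% the rise was 0.00362 CPM (95% bootstrap interval 0 to 0.0391) against 1.06 CPM over all genes, which argues against an even background. Reads of opposite-strand neighbours were also tested. Genes with no such neighbour within 1000 nt still had a median log2 ratio change of 1.09 (95% bootstrap interval 1.00 to 1.16). This argues against neighbours as the whole cause. The median was larger in genes with such a neighbour, 1.38 (1.34 to 1.42), so a part for neighbours stays open. It was 1.17 (1.07 to 1.33) in genes with no gene of either strand within 1000 nt. The bounds of the ext regions are not known, and they may reach past 1000 nt. A difference in RNA or library quality between genotypes, reads reaching past the annotated end, and an effect of Dbp2 loss on 3' end formation stay open.

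The Gini rises could follow read depth per transcript or a shift of whole libraries. Among transcripts whose ORF count changed by under 0.25 log2 units, 3.67% were called (95% Wilson interval 2.20 to 6.07) against 5.62% of all with a tested count, and the share was 14.2% of 113 transcripts whose ORF count was lower by over 1 log2 unit and 16% of 25 whose count was higher by over 1. Calls were thus more frequent where counts changed much, but the interval among stable transcripts reaches the overall share, so depth per transcript stays open. Against depth, the median Gini change was 0.0201 where counts were lower by over 1, 0.0239 where they were stable and 0.0201 where they were higher by over 1, and Gini and count changes were unrelated across 1139 genes (rho -0.0195, permutation p = 0.508). After centring each library on its median, 28 of the 84 rises were called again. Centring takes about the same amount from every transcript, near the median change of 0.0240. Rises close to the threshold are thus lost by construction, and their loss does not show where they came from. Whether the library-wide shift of the index reflects structure in dbp2Δ or library depth was not tested, because the deposited reactivities carry no depth. Each dbp2Δ library had values at more positions than any WT library, and a larger share of these values was at 0.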

How the results depend on the processing

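The separate fits of ORF and ext rows, the separate scaling of ext and ORF columns, the lane values of the ext share, the 20% filter, positions taken per library, the Gini lists and the last 100 valued positions were chosen only after the results were seen. Where they were tested again, the rows, ratios, transcripts and windows named for the size or p of their change kept their direction; the higher count minimum covered 11 of the 20 rows and 8 of the 20 ratios, the windows of 100 nt covered 8 of the 20 windows, and list members were not tested one by one. Smaller changes given relative to the median ORF, such as that of NOP15, can turn with raw totals. Changed rows numbered 1227 with ORF rows and 313 with ext rows fitted alone, which also rescales each class to a median near 0 (0.01 for both), 797 with the lane block, which leaves 1 residual degree of freedom, and 1100 to 2558 with 1 library left out, against 2370. Genes with a changed ext to ORF ratio numbered 195 with regions scaled apart, 751 at a mean count of at least 50 (fewer genes tested) and 7 to 1346 with 1 library left out, against 1187. The ext share difference was 3.82 points within lane 4 and 2.499 to 3.36 with 1 library left out. Called count lists fell from 5 to 0, and Gini lists from 2 to 0, with an estimated inter-gene correlation, and 4 to 8 count lists and 0 mean reactivity lists were called with 1 library left out. Mean reactivity calls numbered 6 with the 20% filter, 2 without a trend, 4 without a filter, 2 with positions per library and 0 to 24 with 1 library left out, against 0. Gini calls numbered 450 with the 20% filter, 726 without a filter, 359 with positions per library, 223 without a trend and 5 to 450 with 1 library left out, against 89. Window calls numbered 51 without a trend, 84 after median centring, 265 without a filter, 58 with a pseudocount of 0.1, 70 in windows of 100 nt and 0 to 321 with 1 library left out, against 138. Within lane 3 the reactivity difference was -0.0297 over whole transcripts, -0.0354 in the first 100 nt, -0.0290 in the middle and -0.0341 in the last 100 nt. With 1 library left out, these ranged from -0.0205 to -0.00334, -0.00646 to 0.0488, -0.0216 to -0.00705 and -0.0233 to -0.0105, and Spearman's rho of replicate agreement from 0.303 to 0.346. The relation of structure and counts, at rho 0.0272, turned to -0.115 over whole transcripts, to -0.0125 over the last 100 valued positions, and ranged from -0.0557 to 0.0889 with 1 library left out. Where no construction is named, the cause was not tested.

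The replicate numbers do not show a pairing: the labels do not say that a number marks a shared culture, only 1 and 3 are shared, and deviations of same-numbered samples correlated at -0.03 and 0.07 in counts and at -0.03 and -0.01 in reactivity. With the number as a replicate block, 2655 rows, 1264 ratios and 4 lists were called, Gini calls were 7, mean reactivity calls 2 and window calls 0, on fewer residual degrees of freedom, and the ext share differed by 2.499 points.

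Planned settings that could not be run were adenines alone and cytosines alone, since bases are not marked, the 60% filter, which left 0 transcripts, and untranslated regions. The library scaling hardly moves the ratio, with 1188 calls with RLE factors and 1189 with raw totals. Ext rows held 217849 to 792977 counts per library, and leaving out a dbp2Δ library leaves 1 sample that is assumed to vary like the WT libraries.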

Other observations

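All lists in this paragraph, and the tests below, were chosen only after the count table was seen. Genes of purine synthesis fell in dbp2Δ in 7 of 8 tested members, by a median of 2.63-fold relative to the median ORF (camera, adjusted p = 1.3e-12; adjusted p = 0.0333 with an estimated correlation), and 7 were lower with each library left out, with raw totals and with the lane as a block. ADE17, a late enzyme of the pathway, fell from 695 ± 96.3 to 113 ± 22.3 CPM and ADE1 from 676 ± 80.9 to 185 ± 37.6 CPM, while ADE16, the paralog of ADE17, was not called (log2 -0.05 relative to the median ORF, adjusted p = 0.0811, edgeR). Histidine synthesis fell in all 3 tested genes, HIS4 from 601 ± 40.5 to 147 ± 23.1 CPM (list adjusted p = 0.000115, camera; adjusted p = 0.268 with an estimated correlation).

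The iron regulon fell in 16 of 19 tested genes, by a median of 2.71-fold (camera, adjusted p = 3.61e-05; adjusted p = 0.375 with an estimated correlation). ENB1, a transporter of the siderophore enterobactin, fell from 169 ± 62.8 to 32.3 ± 9.33 CPM and TIS11, an RNA-binding protein of iron shortage also called CTH2, from 152 ± 81.5 to 12.6 ± 1.62 CPM. WT sample 2 stood apart, with FIT2 at 589 CPM against 67.7 and 156 in the other WT libraries and ARN2 at 347 against 65.8 and 161, and without it the median was -1.12 on the log2 scale in place of -1.44. Without dbp2Δ sample 1 or 3, 8 and 9 passed. Trehalose and glycogen genes rose in 2 of 6, GSY2 and GAC1 (adjusted p = 0.0174, camera; adjusted p = 0.356 with an estimated correlation), and sulphur assimilation and methionine synthesis in 2 of 4, MET17 and MET10 (adjusted p = 0.0174; adjusted p = 0.356 with an estimated correlation). Without dbp2Δ sample 3 no trehalose and glycogen gene passed, and without WT sample 1 only 1 did. The sulphur list includes MET17, whose change may be a strain difference, and the other 3 genes had a median log2 change of 0.40 (range -0.63 to 1.08). Of anaerobic cell wall mannoproteins 6 of 11 fell (adjusted p = 0.0938), TIR1 from 237 ± 164 to 18.9 ± 5.33 CPM. Several of these rest on WT sample 2, as with PAU5 at 68.8 CPM there against 11.2 and 13.8 in the other WT libraries and 11.9 and 10.1 in dbp2Δ, and without it the list median was -1.21 in place of -1.94. Without dbp2Δ sample 1 or 3, 2 of 12 passed. Of lysine synthesis 2 of 5 fell and 1 rose (adjusted p = 0.168). With raw totals the lysine calls were 2 higher and 1 lower, and with ORF rows fitted alone 1 and 1. Raw totals also gave 10 lower and 1 higher in the iron regulon, 2 lower in histidine synthesis, 6 higher among trehalose and glycogen genes, 3 higher in the sulphur list and 5 lower among mannoproteins.

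The near-0 windows that gained reactivity in ribosomal protein transcripts may lie within introns, which many of these genes carry. With no exon table, a start to stop span that is not a multiple of 3 nt served as a mark of a split reading frame. Such a span was found in 48 of 111 ribosomal protein transcripts, of which 25% held a higher window without a library at 0, against 14.3% of the other 63. The odds ratio was 1.99 (95% exact interval 0.688 to 5.95, Fisher's exact p = 0.221). An intron whose length is a multiple of 3 nt leaves the span a multiple of 3, so the other 63 may hold introns too. The comparison can therefore not decide the question. Across all 1426 transcripts with a span the odds ratio was 16.7 (6.77 to 40.6), and among transcripts of other genes 0 of 32 with such a span held a window against 5 of 1283 without (odds ratio 0, interval 0 to 45.1). Introns thus cannot be told from being a ribosomal protein gene.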
